A study of Arabidopsis thaliana with 4 samples.

How the data were processed

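Total RNA from unopened floral buds of Arabidopsis thaliana (accession Col-0) was hybridised to Affymetrix expression arrays, per the labels' protocols, with 500 ng of RNA labelled per sample from plants 24 days after germination. The sample titles describe the buds as young. The series holds 4 arrays: 2 biological replicates of the cdm1 mutant and 2 of the wild type. The growth protocol also mentions moderate drought for some plants, but no label assigns a drought treatment to any of these samples.

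The deposited values are log2 expression values, 1 per probe set and array, as the authors processed them. RMA (background correction, quantile normalisation and median-polish summary of the probes) and the R package affy are named in the submitters' processing notes, and their versions are not given in the sources used here. The log2 scale was read from the values: the arrays run from 2.64 to 14.0, with medians between 7.21 and 7.24. The table holds 22746 probe sets, no missing value and no Affymetrix control probe set. Array scanner files, detection calls and scan dates were not used here, so a hybridisation batch and signal above background were not tested, a fold change with a dim level on one side is a ratio of RMA values only, and the number of arrays limits the precision. RMA pools the arrays during normalisation, which forces similar overall distributions and compresses the fold changes of dim probe sets.

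Probe sets were named through GEO's platform annotation. It gave 1 gene symbol for 13513 probe sets and several for 503, and it did not list 8730. The 13436 single-gene probe sets with a matching gene record were tied to 13286 loci of TAIR10.1, which served only for symbols and gene order, because the sources used here name no genome build. Unlisted probe sets were tested but carry no gene name. CDM1 (locus AT1G68200), all callose synthases and the beta-glucanase A6 have no named probe set and are not analysed here. The mutated gene therefore gives no check of the labels.

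Differential expression was tested with limma 3.58.1 in R 4.3.3. A linear model with genotype as its only term was fitted to the values as deposited, followed by empirical Bayes moderation of the variances. Tests were two-sided, with Benjamini-Hochberg adjustment over all 22746 probe sets and a threshold of 0.05. The model leaves 2 residual degrees of freedom, to which the prior added 4.00. Fold changes are cdm1 minus wild type on the log2 scale, given with the moderated standard error (SE), and group levels are means ± SD of 2 arrays.

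Gene lists (19 lists, 399 loci) were fixed before the data were examined, as were the tests of the genotype difference, the rule for naming genes and the alternatives except 1 given below. Some tests in the closing section were chosen later, as stated there. Each locus was represented by its probe set with the highest mean. Of 402 list entries, 100 were measured, and 9 lists had the 3 members that a set test needs. Those were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 9 lists. The test was repeated with the correlation estimated from the data, and with fry. Fry asks whether a set's genes move, on balance, one way, and does not compare the set with other genes. Named genes were the 10 largest increases and the 10 largest decreases among probe sets of 1 gene past the threshold with no overlap between groups, 9 genes chosen for their known roles (CALS5, CALS12, A6, DYT1, TDF1, AMS, MYB80, MS1 and C3H14, of which AMS and C3H14 were measured), and from each list up to 3 called members or, where none was called, the member with the smallest p. With 2 arrays against 2, an unchanged probe set has no overlap between groups in 33.3% of cases.

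The limma step was tested on simulated data before use. For the comparison of cdm1 with wild type, simulated on 22746 probe sets with 100 changed by each fold, 86% of 2-fold changes and 100% of 4-fold changes were recovered, and 10 of 196 calls were false. Of 200 simulated lists of 11 unshifted members, camera called 1%. Simulated spreads were drawn from the prior that limma fitted to these arrays and were equal in both genotypes. The rates therefore hold only for data that meet limma's assumptions. The simulated genes also varied independently of each other, so this does not test camera on lists of correlated genes. In the data, the estimated correlation was 0.19 for the meiosis list and 0.082 for the tapetum secretion and pollen coat list. For the sporopollenin and exine list it was -0.32. The alternatives were a second quantile normalisation, median centring, removal of the dimmest 33.3% of probe sets, an intensity trend in the variance prior with and without robust estimation, 1 probe set per named locus, the replicate number as a block, leaving out each array (the lone array of a group is then assumed to vary like the other group), ordinary linear-model p-values, an uncorrected p with a 2-fold change, and limma's treat with a 1.2-fold minimum. Removal of probe sets whose names end in _s_at or _x_at, which Affymetrix uses for probes shared between transcripts, was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the test of neighbouring genes and the figures.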

Results

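Gene expression was measured in unopened floral buds of the Arabidopsis cdm1 mutant and of wild type Col-0 plants, with 2 arrays per genotype. CDM1 stands for CALLOSE DEFECTIVE MICROSPORE1, a gene for a CCCH zinc finger protein. Callose is the glucan wall that encloses male meiotic cells and their tetrads and is later digested by beta-glucanases secreted from the tapetum, the nurse tissue of the anther. The comparison asks which transcripts differ between mutant and wild type buds at this stage. The 2 wild type arrays correlated at r = 0.998 across probe sets, which are not independent replicates, and the 2 cdm1 arrays at r = 0.996. Correlations between genotypes were lower, from 0.990 to 0.994. The SD of the log2 difference between replicates was 0.174 for wild type and 0.234 for cdm1. In any pair of arrays at most 42 probe sets held identical values. Array means split by replicate number, at 6.92 (cdm1) and 6.91 (wild type) for replicate 1 and 6.88 in each genotype for replicate 2.

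In cdm1 buds, the largest decreases among probe sets that name 1 gene were in the kelch-repeat F-box genes AT2G29770 and AT2G29830. The largest increases among such probe sets included SHT, which encodes the tapetal spermidine hydroxycinnamoyl transferase that makes pollen wall phenolamides, and the calcium-binding EF-hand protein gene AT4G27280. In all, 303 of 22746 probe sets passed limma's test at an adjusted p of 0.05, 137 of them higher and 166 lower in cdm1. Of these, 146 changed at least 2-fold, 56 upward and 90 downward. Single genes could be named for 78 of the higher and 119 of the lower probe sets, and 97 called probe sets were not listed in the annotation. At an unadjusted p of 0.05, 3470 probe sets passed, against 1137 by chance. With either wild type array left out, limma called 0 probe sets (1619 at an unadjusted p of 0.05 without replicate 1 and 2133 without replicate 2). With cdm1 replicate 2 left out, 1040 passed, 311 of them at least 2-fold, and ordinary linear-model p-values on all 4 arrays gave 1 call.

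**Figure D1:**
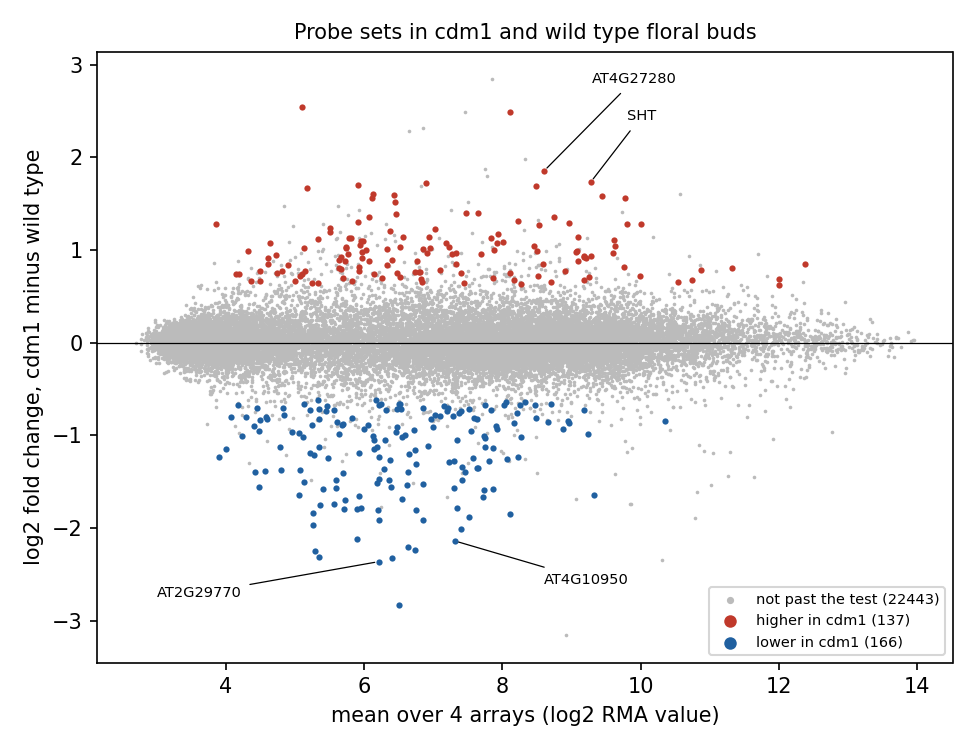
Log2 fold change between cdm1 and wild type (vertical axis) against the mean log2 RMA value over the 4 arrays (horizontal axis), 1 point per probe set. The 137 higher (red) and 166 lower (blue) probe sets passed an adjusted p of 0.05, and grey points did not.

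The 10 largest decreases in named genes ranged from 3.59-fold to 5.15-fold. The kelch F-box gene AT2G29770 fell by 2.36 on the log2 scale (SE 0.10, limma adjusted p = 0.00227), from 7.39 ± 0.092 in wild type to 5.03 ± 0.075 in cdm1 (SD, n = 2 arrays each). A second kelch F-box gene, AT2G29830, fell by 2.33 (SE 0.11), measured by a probe set that Affymetrix marks as shared between transcripts. The tetratricopeptide repeat gene AT5G44330 was 4.71-fold lower, and AT5G17830 was 4.60-fold lower. AT4G10950, a gene of the GDSL lipase family, was 4.41-fold lower and read 8.38 ± 0.019 in wild type and 6.24 ± 0.025 in cdm1. The RNA-binding protein gene AT5G53680 was 4.35-fold lower and AT3G08750 was 3.90-fold lower. The U-box gene AT5G18340 was 3.78-fold lower, AT5G61110 was 3.69-fold lower and AT1G74870 was 3.59-fold lower. Their limma adjusted p-values lay between 0.00227 and 0.00578. Among called probe sets without a listed gene, the strongest decreases were 4.96-fold and 4.75-fold. The largest decrease of all called probe sets, 7.10-fold, was in a probe set of several genes, so no gene is named for it. In cdm1, 5 of the 10 named genes read below 5.32, the limit of the dimmest 33.3% of probe sets, and whether such levels lay above background was not tested.

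The 10 largest increases in named genes ranged from 2.43-fold to 3.61-fold. AT4G27280 rose 3.61-fold (log2 fold change 1.85, SE 0.13, limma adjusted p = 0.00526), from 7.68 ± 0.21 to 9.53 ± 0.091 (SD, n = 2 arrays each). SHT rose 3.32-fold (log2 fold change 1.73, SE 0.24, limma adjusted p = 0.0367), with more spread in wild type, which read 8.41 ± 0.52 against 10.1 ± 0.19 in cdm1. AT3G48450 rose 2.96-fold and AT3G59070 rose 2.87-fold. AT2G42480, of the MATH-domain family, rose 2.64-fold, and AT4G11730, of the P-type ATPase family, rose 2.61-fold. AT5G56570 rose 2.56-fold. A second EF-hand gene, AT2G36180, passed with a log2 fold change of 1.28, reading 4.50 ± 0.024 in cdm1 and 3.22 ± 0.046 in wild type. Both levels are near the lower end of the array, and whether they lay above background was not tested, so no fold is given. AT5G16960 rose 2.43-fold, a call lost without cdm1 replicate 1 (limma adjusted p = 0.0502), and XTH16 also rose 2.43-fold. XTH16 is a xyloglucan endotransglucosylase/hydrolase of the cell wall and read 9.17 ± 0.071 in wild type and 10.4 ± 0.23 in cdm1. Among called probe sets without a listed gene, the strongest increases were 5.82-fold, from a dim wild type level of 3.83 not tested against background, and 5.64-fold.

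**Figure D2:**
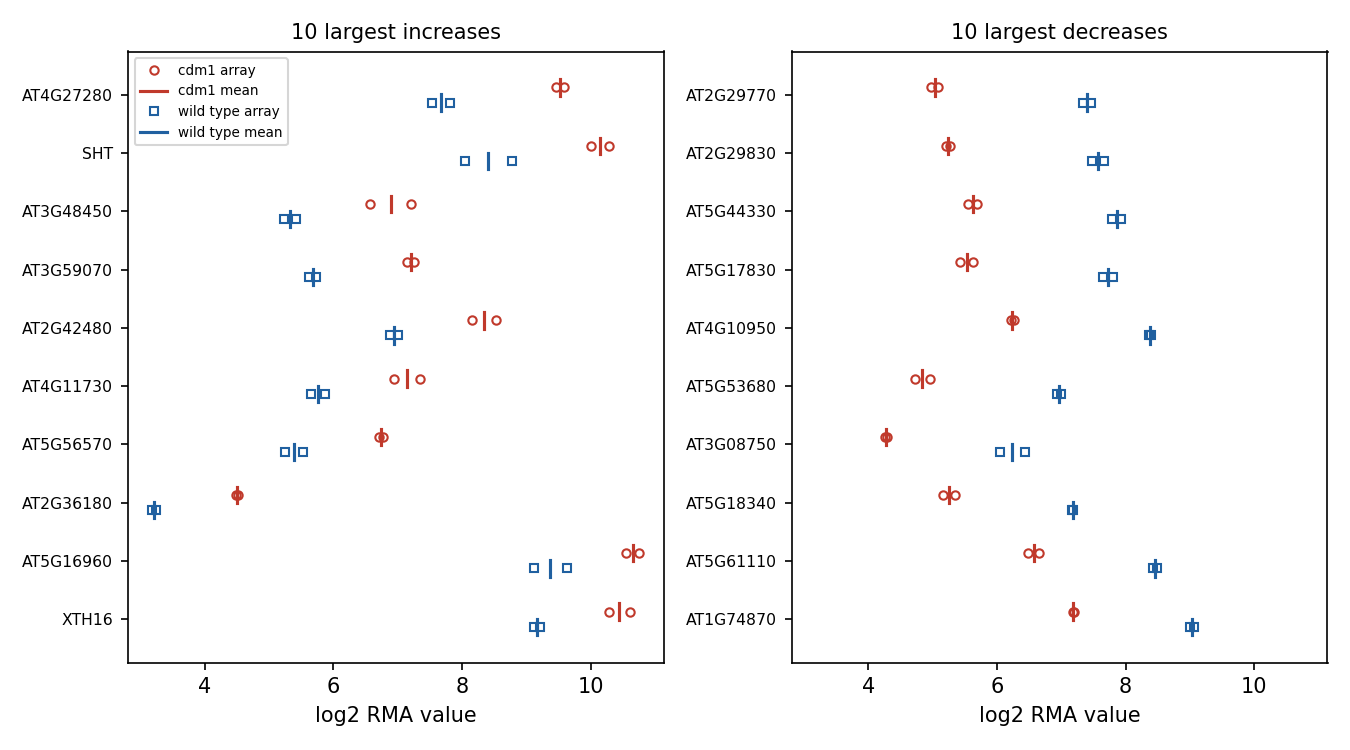
Log2 RMA values of the 10 named genes with the largest increases (left) and the 10 with the largest decreases (right), past an adjusted p of 0.05. Open circles are the 2 cdm1 arrays, open squares the 2 wild type arrays and bars the group means, and in every gene shown the genotypes do not overlap.

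Callose turnover could be followed only through the beta-glucanase family, whose members hydrolyse callose and related glucans. Of its 39 measured members, 3 fell, none rose, and 36 did not pass the test over all probe sets. AT3G24330 was 2.08-fold lower (log2 fold change -1.05, SE 0.15, limma adjusted p = 0.0359), AT3G55780 was 1.77-fold lower (SE 0.10 on the log2 scale, limma adjusted p = 0.0295) and AT3G61810 was 1.60-fold lower (SE 0.090, limma adjusted p = 0.0331). Without cdm1 replicate 1 the call was lost for AT3G24330 (limma adjusted p = 0.0683) and AT3G61810 (0.0550), and AT3G61810 also lost it with the variance trend (0.0603). Without wild type replicate 1 or 2, all 3 lost it, with limma adjusted p-values from 0.131 for AT3G24330 to 0.305 for AT3G61810. Adjustment over a list alone does not correct for the number of lists. In short lists it is close to an unadjusted p, which 3470 of 22746 probe sets passed at 0.05. With p-values adjusted over the list alone, 4 members passed, all lower. The addition was AT4G18340, at a log2 fold change of -1.17 with a larger SE of 0.25. Without cdm1 replicate 1, 2 other members also passed over the list alone, as higher, and without cdm1 replicate 2, 1 did. Without wild type replicate 1, 3 lower members passed, and without replicate 2, 2 did. The family as a whole did not shift (camera adjusted p = 0.788): its mean log2 fold change was -0.063, while its median was 0.021, of opposite sign. Its mean was -0.040 without wild type replicate 1 and -0.086 without wild type replicate 2.

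The lists of pollen wall and tapetum genes were shifted upward with camera's preset correlation, but not with an estimated correlation (adjusted p = 0.495 for each). The 3 measured members of the sporopollenin and exine list were RPG1 (SWEET8), a plasma membrane sugar transporter needed for the primexine, at a log2 fold change of 0.56 (SE 0.15), the galactosyltransferase gene KNS4 at 0.41 (SE 0.11), and the UDP-sugar pyrophosphorylase gene USP at 0.28 (SE 0.10). None passed over all probe sets, and all 3 passed, as higher, when adjusted over the list alone. Without cdm1 replicate 1, 2 did, and without either wild type array, 1 did. These 3 of 20 listed genes were shifted upward (mean 0.41, camera adjusted p = 0.0129). That call was lost with camera's estimated correlation (adjusted p = 0.495). The estimate was negative (-0.32), so positive correlation between the members does not account for the loss. Listed genes such as ACOS5, MS2 and ABCG26 were not measured, so the shift covers the measured genes only. The list of tapetum secretion and pollen coat genes was also shifted upward (mean 0.41, camera adjusted p = 0.0173, adjusted p = 0.495 with an estimated correlation). Of its 11 measured members, out of 27 listed, SHT rose, none fell, and 10 did not pass over all probe sets. Adjusted over the list alone, 5 were higher (SHT, the beta-glucosidase gene ATA27 and the extracellular lipase genes EXL1, EXL3 and EXL5) and 1 was lower (UNDEAD, an aspartic protease gene of the tapetum). ATA27 had a log2 fold change of 0.94 (SE 0.18), EXL5 of 0.99 (SE 0.32) and UNDEAD of -0.64 (SE 0.21). Without wild type replicate 1, EXL5 was at 1.51 and UNDEAD at -0.95, and without replicate 2 they were at 0.46 and -0.32. Adjusted over the list alone, 2 members passed without cdm1 replicate 1 (ATA27 and SHT, higher) and 1 without wild type replicate 2 (SHT). The tapetal lipid transfer protein gene A9 was at 0.12 (SE 0.095; 0.073 without cdm1 replicate 2).

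The list of meiosis genes was shifted downward (mean -0.26, camera adjusted p = 0.0129, adjusted p = 0.495 with an estimated correlation). With all 4 arrays, the 7 measured members, out of 35 listed, had negative log2 fold changes, and none passed over all probe sets. PTD (AT1G12790), a crossover gene, had the smallest p, at a log2 fold change of -0.50 (SE 0.10, limma adjusted p = 0.0882), and was the 1 member that passed when adjusted over the list alone. Without cdm1 replicate 1 or wild type replicate 1, limma called 0 members over the list alone, and without either other array it called 2, PTD and RCK. The helicase gene RCK was at -0.46 (SE 0.15), the meiotic cyclin gene SDS at -0.29 (SE 0.12) and SPO11-1, which makes the meiotic double-strand breaks, at -0.082 (SE 0.18). Without wild type replicate 1, RCK was at -0.29, SDS at -0.17 and SPO11-1 at 0.13, of opposite sign. SPO11-1 was also positive without cdm1 replicate 2, at 0.085. With cdm1 replicate 2 left out, none of the 3 list shifts passed: the adjusted p was 0.0612 for the meiosis list, 0.0612 for the tapetum list and 0.0959 for the exine list.

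**Figure D3:**
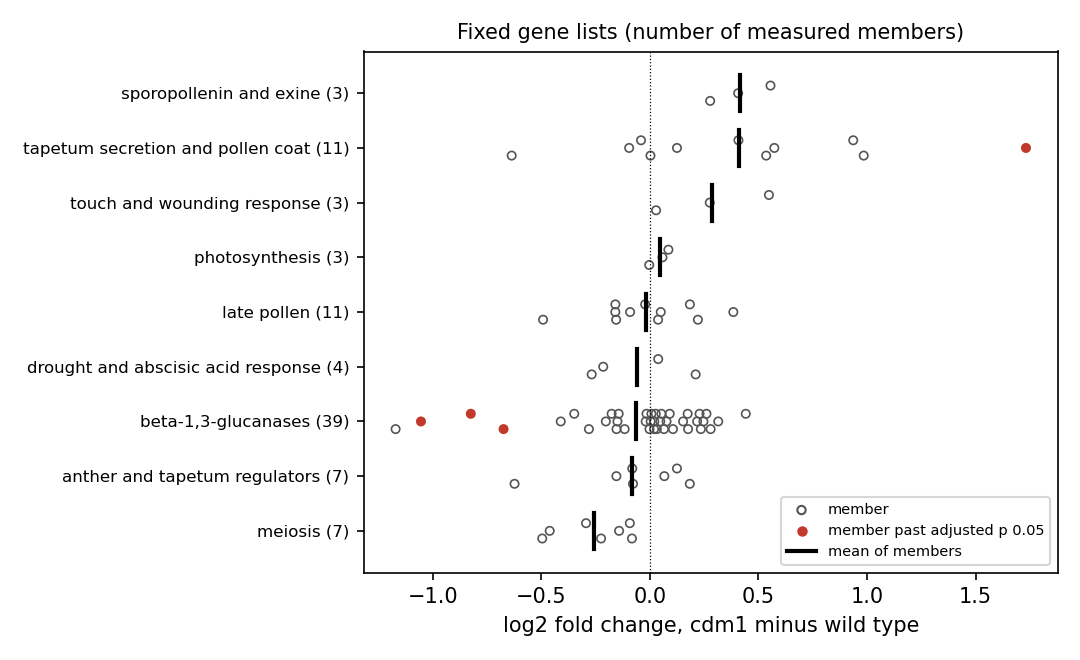
Log2 fold changes between cdm1 and wild type of the measured members of each fixed list with at least 3 of them (1 circle per gene, filled if past an adjusted p of 0.05 over all probe sets). Bars are list means, from -0.26 for meiosis to 0.41 for the exine and tapetum lists.

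Of the regulators of anther development, none passed the test over all probe sets in the reported fit. Of 7 measured members, ROXY2, a glutaredoxin gene of early anther development, had the smallest p, at a log2 fold change of -0.62 (SE 0.10, limma adjusted p = 0.0597). ROXY2 did pass after quantile normalisation (0.0460), median centring (just under the threshold) and robust estimation with the trend (0.0411), and over all alternatives its limma adjusted p ran from 0.0411 to 0.453. It was the 1 member that passed, as lower, when adjusted over the list alone, which it did not without wild type replicate 1. The list did not shift (mean -0.080, camera adjusted p = 0.788). AMS, a central transcription factor of the tapetum, read 11.3 ± 0.024 in cdm1 and 11.1 ± 0.0038 in wild type, a log2 fold change of 0.18 (SE 0.089, limma adjusted p = 0.395). C3H14 (AT1G66810), the closest relative of CDM1, was at 0.12 (SE 0.15, limma adjusted p = 0.772), and the other measured tandem zinc finger gene, TZF8, was also at 0.12 (SE 0.12). C3H14 was at -0.035 without cdm1 replicate 1 and at -0.026 without wild type replicate 2, where TZF8 was at 0.0085.

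Markers of other tissues and of handling gave no called member with all 4 arrays. The 11 late pollen genes had a mean log2 fold change of -0.018 (camera adjusted p = 0.888), with PLIM2A at -0.49 (SE 0.18; -0.24 without wild type replicate 1 and -0.75 without wild type replicate 2, where it passed over the list alone). The 3 photosynthesis genes had a mean of 0.047 (camera adjusted p = 0.788), with LHCB4.2 at 0.085. The 4 drought and abscisic acid genes had a mean of -0.058 (camera adjusted p = 0.801), with COR15B at -0.27. The 3 touch and wounding genes had a mean of 0.28 (camera adjusted p = 0.186). Of these, CML38 was at 0.55 (SE 0.15) and was the 1 gene that passed, as higher, when adjusted over the list alone, a call lost without cdm1 replicate 2 and without wild type replicate 2. This list did pass without wild type replicate 1 (mean 0.41, camera adjusted p = 0.0289). Too few members were measured for a set test of the carpel and ovule list (INO at 0.23 and SPT at -0.022), the floral organ list (PTL at 0.065 and RBE at -0.028), the heat shock list (ROF2 at 0.35 and HSP22 at 0.15), the secondary wall list (IRX10 at -0.13 and IRX15 at 0.10), the jasmonate list (OPCL1 at 0.50, SE 0.15, limma adjusted p = 0.213, and 0.29 without wild type replicate 1) and the circadian clock list (GI at -0.46, SE 0.095, limma adjusted p = 0.103). ROF2 was at 0.10 without cdm1 replicate 1, and without cdm1 replicate 2 it passed at 0.60 (limma adjusted p = 0.0464). Adjusted over the list alone, OPCL1 passed as higher and GI as lower, each as the 1 measured member of its list, and OPCL1 did not without wild type replicate 1. Signs turned for SPT (0.028) and RBE (0.13) without cdm1 replicate 2, for PTL (-0.081) without cdm1 replicate 1 and for HSP22 (-0.016) without wild type replicate 1. SPT (0.035) and PTL (-0.010) also turned without wild type replicate 2, and RBE (0.092) without wild type replicate 1. Leaving out 1 array moved INO to 0.11, COR15B to -0.15 and IRX15 to 0.018 without wild type replicate 2, LHCB4.2 to 0.023 without cdm1 replicate 2 and IRX10 to -0.070 without cdm1 replicate 1. PLIM2A, INO, RBE, HSP22 and IRX15 also read below 5.32, and no such level was tested against background. No member of the callose synthase, salicylic acid defence or tetrad pectin lists was analysed here.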

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

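The 303 probe sets kept their direction after a second quantile normalisation and after median centring. The variance trends and the block leave fold changes as they are, and left-out arrays cannot turn probe sets whose groups do not overlap. Quantile normalisation gave 360 calls, of which 301 were shared with the reported ones, median centring 336, the variance trend 319, removal of the dimmest 33.3% 252, an unadjusted p with a 2-fold change 226, and removal of shared probe sets, an alternative chosen after seeing the data, 282. Robust estimation with the trend gave 465 calls, 299 of them shared, for a cause not tested, and 1 probe set per named locus gave 200, with fewer probe sets tested. Ordinary linear-model p-values gave 1 call (2261 at an unadjusted p of 0.05), which was not among the 303. Leaving out 1 array gave between 0 (limma without either wild type array, 1619 and 2133 at an unadjusted p of 0.05) and 1040 calls (without cdm1 replicate 2), and between 0 and 311 of at least 2-fold. With the replicate number as a block, limma gave 0 calls, 0 of them 2-fold (3110 at an unadjusted p of 0.05). Deviations of same-numbered arrays from group means correlated at -0.066, but array means split by number, so pairing is left open. The block leaves 1 residual degree of freedom. With the block, 3 lists still passed. Treat kept 101 of the 146 2-fold calls. The 3 list shifts held under quantile normalisation, centring, the dim filter, the trend and 1 probe set per locus. With the estimated correlation or with fry, 0 lists passed, at the same means (-0.26 for meiosis, 0.41 for exine and 0.41 for tapetum). The cause was not tested, but the exine estimate was negative (-0.32), so positive correlation does not account for the exine loss with camera. Leaving out 1 array gave 0 (without cdm1 replicate 2) to 4 lists (without wild type replicate 1), with means of -0.33 to -0.18 for meiosis, 0.37 to 0.46 for exine, 0.32 to 0.51 for tapetum and 0.16 to 0.41 for touch and wounding. Uncalled means changed sign for drought (0.011 without cdm1 replicate 1, range from -0.13), late pollen (0.016 without cdm1 replicate 2 and 0.028 without wild type replicate 1, range from -0.064) and photosynthesis (-0.0025 without wild type replicate 1, range up to 0.096). Only 23 of the 39 named genes passed in the reported fit, and only these could lose a call. For the 39 named genes, 343 of 424 alternative values kept their side of the threshold and their sign, 73 lost the call and 4 gained it (ROXY2 with 3 alternatives, ROF2 with 1). The other 4 changed sign, all uncalled: without cdm1 replicate 1 and without wild type replicate 2, C3H14 was at -0.035 and -0.026, and PTL at -0.081 and -0.010, against 0.27 and 0.21 without cdm1 replicate 2. Of the 73 losses, 23 each came from the block and from leaving out either wild type array, 3 from leaving out cdm1 replicate 1 and 1 from the variance trend. Robust estimation was not run for the lists, the touch and wounding list had too few members after the dim filter, and no alternative was run for CDM1, whose probe set is not named here. Low signal limits the late pollen list, 8 of 11 being dim.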

Other observations

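The tests of meiocytes, tapetal cells and bud age, and the plastid values, were chosen after the results were seen. The test of neighbouring genes was not among those fixed before the data were examined. Other called genes outside the fixed lists are given as single values, chosen after these were seen and not tested as a group. INP1, which is needed to form pollen apertures, was 2.07-fold lower in cdm1 (log2 fold change -1.05, SE 0.12, limma adjusted p = 0.0224). The histone deacetylase gene HDA7 was 2.47-fold lower (limma adjusted p = 0.00995), and the reproductive meristem gene REM22 was 1.60-fold lower (limma adjusted p = 0.0420, and 0.0782 without cdm1 replicate 1). The MADS-box gene AGL89 passed as lower, reading 3.43 ± 0.20 in cdm1 and 4.58 ± 0.11 in wild type, both dim and not tested against background, so no fold is given. The thionin gene THI2.2 was 3.11-fold lower, from 10.1 ± 0.0070 to 8.50 ± 0.22 (SD, n = 2 arrays each).

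Among the higher calls, the pectin methylesterase gene PME41 (listed as ATPMEPCRB) rose 2.13-fold, and the flavonol glycosyltransferase gene UGT79B6 (AT5G54010) rose 1.96-fold. The lipid transfer protein genes AT4G14815 and AT1G66850 rose 1.91-fold and 1.80-fold, the latter to 12.8 ± 0.056. The actin gene ACT11 rose 1.58-fold and the isocitrate lyase gene ICL 1.88-fold. Without cdm1 replicate 1 the call was lost for AT1G66850 (limma adjusted p = 0.0579) and ACT11 (0.0638), and without either wild type array limma called none of the genes named here. Of 69 plastid-encoded probe sets, 1 was called, psaC at 1.83-fold lower (limma adjusted p = 0.0351, and 0.0674 without cdm1 replicate 1). Their median log2 fold change was -0.19, which depended on cdm1 replicate 1. Without that array it was -0.057, and without cdm1 replicate 2 it was -0.31, with 17 called lower.

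The 90 probe sets at least 2-fold lower had a median log2 fold change of -1.44. Fewer meiocytes in the mutant buds would lower the meiosis list, whose median was -0.22 (SD over members 0.17). Its gap to -1.44 decides little, because the 90 were chosen for a 2-fold fall and the list was not. RCK (mean 5.34) and SPO11-1 (5.39) also lie near the dim limit of 5.32, where RMA compresses fold changes. Fewer meiocytes are therefore left open. The tapetum secretion list had a median of 0.41 (SD over members 0.65), with 8 members positive and 3 negative. A list that did not fall argues against fewer tapetal cells alone. Older buds, left open below, could raise this list and hide such a loss, so fewer tapetal cells are not excluded. A loss of one stage, such as the tetrad, and an effect of the genotype within cells may both account for the pattern, and neither was tested.

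Lower genes lay next to each other more often than in random placements, in a test not fixed in advance. Among 13217 named nuclear loci in chromosome order, the 117 lower genes formed 9 neighbouring pairs, against a mean of 1.02 and at most 6 in 10000 random placements (one-sided permutation p = 0.0001, the smallest these can give). The 78 higher genes formed 1 pair (permutation p = 0.4). Pairs included AT1G15320 with AT1G15330, AT2G33000 with AT2G33010, and the kelch F-box run in which AT2G29770, AT2G29780, AT2G29800, AT2G29820 and AT2G29830 all fell. AT2G29790, between them, read 3.02 in cdm1 and 3.17 in wild type, too dim to show whether it fell. The kelch run holds the largest named decreases, AT2G29770 and AT2G29830, so the p-value is not independent of values already seen. Probe sets marked as shared between transcripts do not account for this, with 8 pairs left after their removal against a random mean of 1.01, nor does the region around CDM1 on chromosome 1, with 7 pairs outside that chromosome against 0.668. Of the 200 named loci nearest to CDM1, 2 were called, against 2.95 by chance. A candidate explanation is that tandem gene copies share expression in the same cells, but sequence similarity, and cross-hybridisation in probe sets without a shared mark, were not tested.

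With camera's preset correlation the exine and tapetum lists were higher and the meiosis list was lower, but none passed with an estimated correlation (adjusted p = 0.495 for each), with fry or without cdm1 replicate 2. If the shifts hold, they may follow from slightly older buds in the mutant samples. Older buds could raise late pollen genes, whose mean was -0.018, but 8 of the 11 lie in the dimmest 33.3% of probe sets. The other 3 had a mean of -0.088, which goes against a rise of late pollen genes but rests on few of them. Whether a slight age difference between young buds would move these genes was not tested. Bud age and genotype therefore cannot be told apart here.

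The 4 arrays allow 3 splits into 2 and 2, too few for a share under 0.05. The real split gave 303 calls, the only 1 of the 3 with as many, and the highest other gave 0 (568 at an unadjusted p of 0.05 in limma). Each other split mixes the genotypes on both sides, so a genotype difference adds to its spread and lowers its calls. The counts therefore do not measure chance.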
